A study of Mus musculus with 6 samples.

How the data were processed

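Whole-transcriptome RNA sequencing was analysed for 6 libraries of A375, an established human melanoma cell line. Per the labels' protocols, the cells received lentivirus carrying Cas9 and a guide RNA, were selected with puromycin at 10 µg/mL, and were collected 7 days after selection. Total RNA (1 µg per sample) was made into strand-specific libraries and read as 150 bp pairs on an Illumina NovaSeq. The titles place 2 libraries each in the control group (guides against LacZ or Luciferase, per the series design), the ABCE1 group and the YAE1 group. The labels do not say whether the 2 libraries of a group carry different guides or come from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The organism field of the labels reads Mus musculus, while the cell type field reads human and the submitters' processing notes name GRCh37, a human build. The genotype field of the second ABCE1 and YAE1 libraries carries a gene name ending in 2, so the groups were taken from the titles.

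The authors deposited 1 table of FPKM values (fragments scaled to the length of the gene model and to the library's fragments) with a column per library and 62492 gene identifiers. The aligner, the counting program and the annotation release are not given in the sources used here. The table gives Ensembl identifiers without gene symbols. The reference tables used here are for mouse, and 0 of the 62492 identifiers matched them. No identifier was therefore given a gene name. The rows of ABCE1, YAE1 and LTO1, the MHC class I and nonsense-mediated decay lists and the other symbol lists (37 lists in all), which had been fixed before the data were examined, were not analysed here, and the targeted genes could not be used to check the labels. For the same reason the rule that chose genes by symbol was narrowed after the table was opened. The 2 identifiers that rose and the 2 that fell were named whose smaller change in the 2 knockouts was largest, among genes past the threshold in both, with a mean of at least 5 FPKM and no overlap between knockout and control libraries. Positions in the genome were not analysed here.

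The low FPKM values of a gene were whole multiples of 1 step, so the fragment numbers behind them were worked out. The ratios between libraries gave their relative totals, the common step over genes gave the totals, and the smallest gene length that made every value a multiple of 0.5 fragments gave the numbers per gene. All 38269 genes above 0 in at least 1 library met this, with a tolerance of 2e-05 steps. The recovered totals were 18399718 and 17614506 fragments for the controls, 15713011 and 17687994 for the ABCE1 libraries, and 16815389 and 17065739 for the YAE1 libraries. The numbers per gene added up to at least 99.4% of these totals, so the FPKM scale counts fragments assigned to genes. A factor common to a gene's 6 values stays unknown, which leaves fold changes untouched. In data simulated with known numbers, 99.4% of 1911 genes with a mean of at least 20 fragments came back exactly. Genes kept for the tests had a median of 542 recovered fragments per library, a counting error of 4.3%, and a 5th percentile of 15.8 fragments, a counting error of 25.2%. These errors cover counting only.

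Genes were kept when their mean over the 6 libraries was at least 1 FPKM (12578 genes). Differences were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (a mean per group, all 6 libraries in 1 fit, eBayes with a trend, Benjamini-Hochberg adjustment over the genes kept, threshold 0.05). Fold changes on this scale understate the change of low genes. An exact permutation test of 2 libraries against 2 cannot reach p = 0.05 and was not used. The fit had 3 residual degrees of freedom and 3.6 added by moderation. On libraries simulated for the ABCE1 comparison over 12578 genes, with 200 genes changed in negative binomial counts of dispersion 0.000928, the test recovered 70.1% of the changes of 1.5-fold, 85.1% of 2-fold and 100% of 4-fold, with 17 false calls. In this 1 simulated data set the false calls were a larger share of the calls than the threshold of 0.05. It used 1 dispersion for all genes and few changed genes, whereas 57.9% of genes were called with ABCE1 guides. These rates need not hold for the data.

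Since the symbol lists were not usable, 3 lists of identifiers were added after the table was opened, from the human cell-cycle marker pairs that ship with the Bioconductor package scran. Each pair names a gene that is above another in 1 phase. A gene entered the list of G1, S or G2M when it was the higher member in at least 90% of at least 10 pairs of that phase, and of no other phase. The lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over 9 tests (3 lists, 3 comparisons), with camera at an estimated correlation and with fry. With an estimated correlation, camera also tests on only the 3 residual degrees of freedom of the fit. Agreement that shared controls give when no gene changes was taken from 100 simulated data sets without effects. Replicates were compared by Pearson correlation and by a chi-square per gene on recovered fragments, where sampling noise alone gives about 1. The values were 2.47 (controls), 2.81 (ABCE1) and 5.56 (YAE1) within groups and 24.2 to 83.8 between groups. No pair of libraries therefore differed by sampling noise alone. The YAE1 pair differed most, while the main fit used a spread shared by all groups.

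Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, centring on the median gene, quantile normalization, only the 4 libraries of a comparison, robust moderation, the replicate number as a block, and leaving out each library. Leaving out mitochondrially encoded genes was not run because rows carry no names. Alternatives added after seeing the data were limma voom on the recovered fragments, stricter cell-cycle lists (the higher member in every one of at least 20 pairs), leaving out the 20 genes with the highest mean FPKM, and setting each knockout against its own control library. Figures were drawn with matplotlib 3.10.9.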

Results

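The transcriptomes of A375 melanoma cells were compared 7 days after selection for guides against ABCE1 or YAE1 and for control guides, with 2 libraries per group. ABCE1 is an iron-sulfur ATPase that separates ribosomal subunits after termination. YAE1 acts with LTO1 as an adaptor for delivering the iron-sulfur cluster to ABCE1. The title of the series places both genes in an LTO1 complex and asks about nonsense-mediated RNA decay and MHC class I in tumour cells. The deposited FPKM table names genes by Ensembl identifier alone, so the targeted genes, MHC class I genes and decay targets were not analysed here, and genes are described by identifier, by abundance and by cell-cycle list. Total depth worked out from the values was 15713011 to 18399718 assigned fragments per library. Libraries of the same group correlated at r = 0.992 to 0.994 over the log2 values of 12578 genes, and libraries of different groups at 0.942 to 0.98. The first principal component held 69.2% of the variance and placed the controls at -35.6 and -33.3, the YAE1 libraries at 10.9 and 10.1 and the ABCE1 libraries at 24.4 and 23.5. The second component (18.9%) placed the ABCE1 libraries at 14.7 and 12.3, the YAE1 libraries at -19.4 and -15.7 and the controls at 4.0 and 4.1.

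The first comparison asked what ABCE1 guides change relative to control guides. With ABCE1 guides 4715 genes were higher and 2563 were lower, 57.9% of 12578 (limma, adjusted p under 0.05). On the log2(FPKM + 1) scale 553 of these rose and 206 fell at least 2-fold, while a pseudocount of 0.1 gave 975 and 308 and voom on recovered fragments 1010 and 310. Centring each library on its median gene gave 393 and 301, and quantile normalization 361 and 276. ENSG00000095752 rose 26.0-fold in mean abundance, from 4.66 ± 0.283 FPKM in the controls to 121 ± 5.58 FPKM (SD, n = 2 each), a log2 change of 4.43 ± 0.07 (SE, limma adjusted p = 2.9e-06). ENSG00000175426 rose 10.9-fold, from 2.91 ± 0.57 to 31.8 ± 6.77 FPKM (log2 change 3.06 ± 0.15, limma adjusted p = 2.4e-05). Among genes that fell, ENSG00000117724 went from 56 ± 3.36 to 11.3 ± 1.57 FPKM (log2 change -2.22 ± 0.15, limma adjusted p = 6.7e-05), and ENSG00000148773 went from 65.7 ± 0.38 to 17.5 ± 1.06 FPKM (log2 change -1.86 ± 0.08, limma adjusted p = 1.9e-05). Both of the latter are members of the G2M list.

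Abundant genes were more often lower with ABCE1 guides. Of the 777 genes with a mean of at least 50 FPKM, 378 fell and 183 rose with ABCE1 guides, with a median log2 change of -0.135. Of the 2247 genes at 1 to 2 FPKM, 193 fell and 681 rose, with a median of 0.133. The median over all tested genes was 0.098, and centring each library on its median gene shifted it by -0.139. After centring, 491 abundant genes were lower and 127 higher, and with quantile normalization 295 and 247. The excess of higher genes at 1 to 2 FPKM did not hold in the same way: centring gave 466 higher and 359 lower, and quantile normalization 383 higher and 441 lower. Over all genes 64.8% of calls were higher on the authors' scale, 64.7% with voom on recovered fragments and 64.5% without the 20 most abundant genes. Voom used the same library totals, so it did not test the scaling. Centring, which removes a general shift whatever its cause, gave 3271 higher and 3915 lower (45.5% higher), with a median log2 change of -0.04. Quantile normalization, which forces the same distribution on every library, gave 49.0% higher.

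The second comparison asked the same of YAE1 guides. Here 4303 genes were higher and 2214 lower, 51.8% of those tested (limma, adjusted p under 0.05). With only the 4 libraries compared, the counts were 4038 and 2047 for YAE1 guides, and 4860 and 2703 for ABCE1 guides. On the log2(FPKM + 1) scale 277 rose and 187 fell at least 2-fold, while a pseudocount of 0.1 gave 696 and 306 and voom 740 and 307. Centring turned this split to 198 and 254, and quantile normalization to 186 and 243. The 4 named genes were chosen for their changes in both knockouts. ENSG00000095752 rose 13.7-fold to 64 ± 5.61 FPKM (SD, n = 2, log2 change 3.52 ± 0.07, limma adjusted p = 7.6e-06). ENSG00000175426 rose 10.2-fold to 29.7 ± 2.16 FPKM (log2 change 2.98 ± 0.15, limma adjusted p = 5.1e-05). ENSG00000117724 fell to 6.93 ± 1.72 FPKM (log2 change -2.86 ± 0.15, limma adjusted p = 5.3e-05) and ENSG00000148773 to 18.4 ± 2.32 FPKM (log2 change -1.78 ± 0.08, limma adjusted p = 4.2e-05). Of the genes of at least 50 FPKM, 275 fell and 243 rose (median log2 change -0.018), and of those at 1 to 2 FPKM, 164 fell and 630 rose (median 0.152). Centring kept these directions, with 353 lower and 170 higher among the abundant genes and 242 lower and 430 higher at 1 to 2 FPKM. With quantile normalization they turned, to 257 lower and 292 higher among the abundant genes and 334 lower and 284 higher at 1 to 2 FPKM. Over all genes centring gave 3014 higher and 3124 lower, 49.1% higher against 66.0%, and quantile normalization 52.2%.

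**Figure D1:**
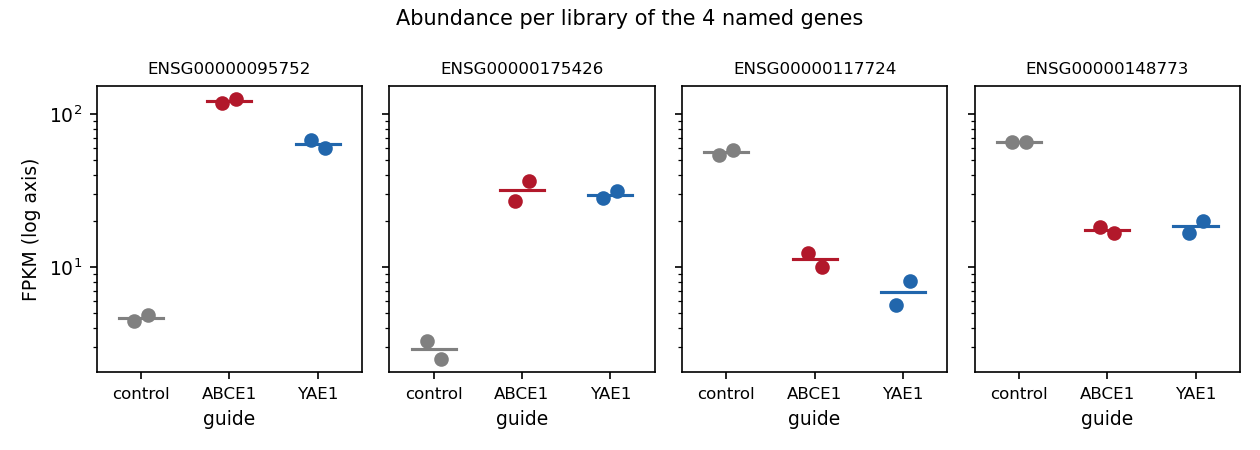
FPKM (log axis) of the 4 named genes in each library. Points are single libraries and lines are the means of 2. By the rule that chose them, ENSG00000095752 and ENSG00000175426 lie above both controls in all 4 knockout libraries, and ENSG00000117724 and ENSG00000148773 lie below both controls.

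More genes of each of 3 cell-cycle lists were called lower than higher in both knockouts. In each knockout most members of the G1 and G2M lists were not called lower, although the list medians were below 0. The lists' difference from other genes passed camera with a preset correlation and was lost with an estimated one (adjusted p = 0.13 to 0.17). Relative to the median of all tested genes, the medians of the S list (DNA replication), the G2M list (the approach to and passage through mitosis) and the G1 list lay at -0.31, -0.22 and -0.18 with ABCE1 guides and at -0.28, -0.21 and -0.17 with YAE1 guides. Of 177 measured genes of the S list, 89 fell and 30 rose with ABCE1 guides, and 58 did not pass the test, with a median log2 change of -0.215. With YAE1 guides 94 fell, 27 rose and 56 did not pass (median -0.184). Of 152 genes of the G2M list, 69 fell and 42 rose with ABCE1 guides (median -0.119), and 69 fell and 33 rose with YAE1 guides (median -0.119). Of 198 genes of the G1 list, 83 fell and 61 rose with ABCE1 guides (median -0.079), and 81 fell and 50 rose with YAE1 guides (median -0.071). Adjusted over the list alone, the counts with ABCE1 guides were 92 lower and 32 higher for S, 69 and 45 for G2M, and 84 and 62 for G1. With YAE1 guides they were 95 and 27 for S, 70 and 35 for G2M, and 83 and 51 for G1. Against all other genes, camera with a preset correlation gave adjusted p = 1.2e-09 (S), 3e-05 (G2M) and 0.00061 (G1) for ABCE1 guides, and 1.4e-11, 9.3e-08 and 3e-05 for YAE1 guides. With an estimated correlation none of these calls held: camera adjusted p = 0.13 for S in both knockouts, 0.17 and 0.15 for G2M, and 0.15 for G1 in both. That setting also rests on only 3 residual degrees of freedom, so the loss cannot be put down to correlation alone. On balance the genes of each list moved down (fry, adjusted p = 0.00065 for S in both knockouts, 0.0024 and 0.002 for G2M, 0.0025 and 0.002 for G1). The order of the lists depended on their definition. With stricter lists the medians for ABCE1 guides were -0.271 (G1), -0.139 (S) and -0.446 (G2M), and for YAE1 guides -0.200, -0.130 and -0.578. The G1 median with ABCE1 guides was -0.046 without ABCE1 replicate 1. With no filter the G2M median with ABCE1 guides was -0.037, and with a mean of at least 5 FPKM the G2M median with YAE1 guides was -0.212.

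**Figure D2:**
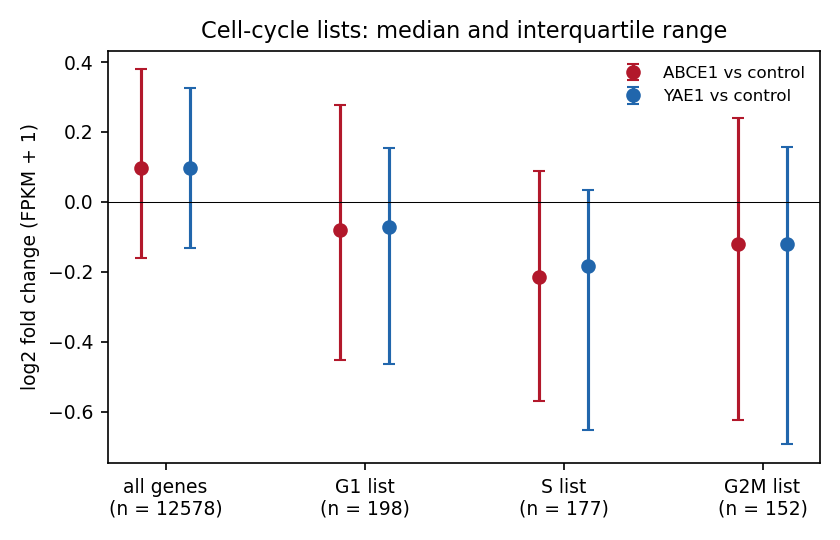
Log2 fold change (FPKM + 1) of all 12578 tested genes and of the members of the G1, S and G2M lists, for ABCE1 and YAE1 guides against control. Points are medians and bars span the interquartile range over genes. The median of all genes lies at 0.098 and 0.096, and each list's median lies below 0.

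The 2 knockouts changed many genes in the same direction. The control guides were against LacZ or Luciferase, and no group had guides against another gene of these cells. Whether the shared changes are particular to ABCE1 and YAE1 was therefore not tested. Called higher in both were 3297 genes and called lower in both 1613, while 123 were called in opposite directions. Centring on the median gene turned the shared counts to 2085 higher and 2447 lower. Independent lists of these sizes would share 1613 higher and 451 lower genes and give 1707 opposite calls. Data simulated without effects, with simulated controls shared by both comparisons, gave at most 2 shared higher and 1 shared lower genes. No gene differed in these data, so few calls could arise. Their counts are not a chance level for lists of the observed sizes. Across genes, which are not independent replicates, the changes correlated at r = 0.811 (Spearman 0.77). The simulated data gave a mean r of 0.501, which is what shared controls produce when there is no effect. It is not their part of 0.811. The covariance was 0.18 against 0.00571 in the simulated data, where only noise in the shared controls adds to it, a difference of 0.175. With each knockout set against its own control library, an alternative chosen after seeing the data, the correlation was 0.746 and 0.755 in the 2 possible assignments and the covariance 0.172 and 0.174. These fits gave 2211 and 2297 genes higher in both, against 933 and 978 for independent lists, and 1101 and 1129 lower in both, against 247 and 256. Each such part holds 1 control library, assumed to vary like the other groups.

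**Figure D3:**
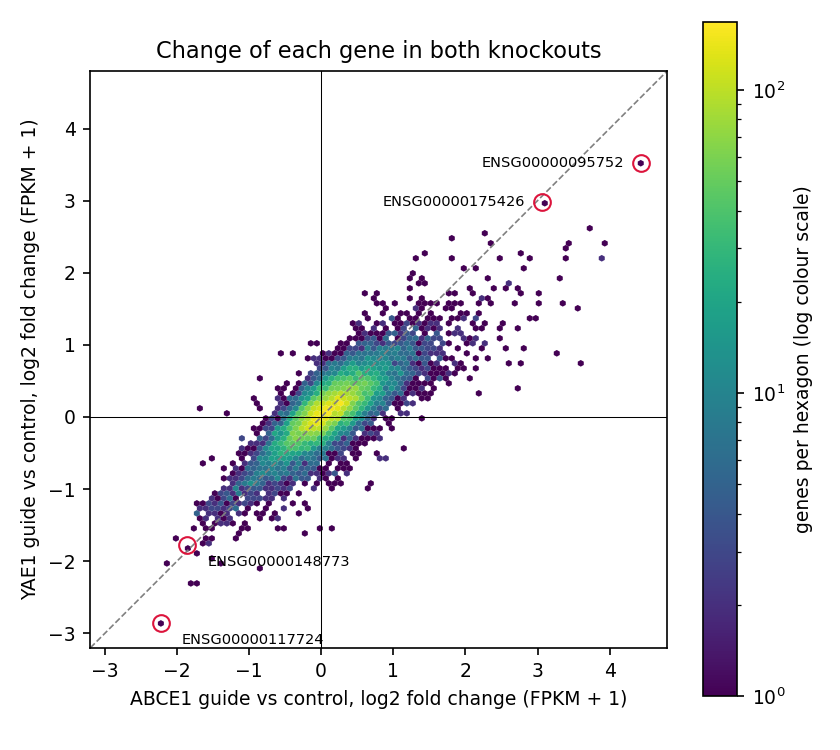
Log2 fold change (FPKM + 1) of 12578 genes with ABCE1 guides (x axis) and YAE1 guides (y axis) against control, as hexagons coloured by the number of genes on a log scale. The dashed line marks equal change and circles mark the 4 named genes, which were chosen for changing in the same direction in both knockouts.

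The third comparison set the 2 knockouts against each other. With YAE1 guides 1928 genes were higher and 2351 lower than with ABCE1 guides (limma, adjusted p under 0.05), of which 10 and 95 differed at least 2-fold on the log2(FPKM + 1) scale, 39 and 174 with a pseudocount of 0.1 and 47 and 189 with voom. Among the 3297 genes higher in both knockouts, 1202 differed between them, and 893 of these were further from control with ABCE1 guides and 309 with YAE1 guides. Among the 1613 genes lower in both, 442 differed, 307 of them further from control with ABCE1 guides and 135 with YAE1 guides. ENSG00000095752 was lower with YAE1 than with ABCE1 guides (log2 difference -0.91 ± 0.07, limma adjusted p = 0.0018), as was ENSG00000117724 (-0.64 ± 0.15, limma adjusted p = 0.021). The call for ENSG00000117724 was lost without ABCE1 replicate 1 (-0.51, limma adjusted p = 0.11), without YAE1 replicate 1 (-0.42, limma adjusted p = 0.056) and with no filter (limma adjusted p = 0.11). ENSG00000175426 (-0.08 ± 0.15, limma adjusted p = 0.71) and ENSG00000148773 (0.07 ± 0.08, limma adjusted p = 0.54) did not pass. Of the genes of at least 50 FPKM, 261 were higher and 97 lower with YAE1 guides (median log2 difference 0.073), and with quantile normalization 215 and 144. None of the cell-cycle lists differed from other genes in camera (adjusted p = 0.57 for G1, 0.73 for S and 0.57 for G2M), with median differences of -0.027, -0.013 and -0.036. The S list's median was below 0 while camera placed it above the other genes. Single members were called, as were 34% of all tested genes: 30 were higher and 51 lower in the G1 list, 28 and 24 in the S list, and 21 and 35 in the G2M list. Such calls are therefore not particular to these lists. As a test of change in either direction, fry gave adjusted p = 3.6e-05, 0.00024 and 0.00036. It does not compare a list with other genes. The counts of genes that differed fell to 835 higher and 976 lower without ABCE1 replicate 1, to 919 and 1044 without ABCE1 replicate 2, and to 907 and 1184 with no filter. Centring on the median gene turned the split to 2395 higher and 1882 lower.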

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

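The tests of the 20 most abundant genes, of depth, of a uniform background and of the S list against the G1 list were chosen after the results were seen. Centring was among the alternatives fixed beforehand, but its use as a test of scaling was also chosen after the results were seen. The cell-cycle lists themselves were chosen after the table was opened. No group had the 4 libraries needed to look for outlying samples.

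ENSG00000095752 rose less with YAE1 guides than with ABCE1 guides (difference of the log2 changes -0.91, limma adjusted p = 0.0018). ENSG00000117724 fell further with YAE1 guides than with ABCE1 guides (difference -0.64, limma adjusted p = 0.021), a call that was lost without ABCE1 replicate 1 (-0.51, limma adjusted p = 0.11), without YAE1 replicate 1 (-0.42, limma adjusted p = 0.056) and with no filter (limma adjusted p = 0.11).

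More genes were higher than lower in both knockouts, 64.8% of calls with ABCE1 guides. The 20 most abundant genes of each library held 16.3% and 16.1% of the summed FPKM with ABCE1 guides and 16.4% in both controls. Leaving out the 20 with the highest mean therefore hardly moved the scale (ABCE1 median log2 change 0.098 to 0.096), and 64.5% of ABCE1 calls were higher. With YAE1 guides 67.2% were higher against 66.0%. These 20 genes do not account for the excess, but the other abundant genes were not tested in this way. After centring on the median gene the share was 45.5%, but centring removes a general shift whatever its cause. An effect of the scaling therefore cannot be told apart from a general rise. Values scaled to a library total carry no information on RNA per cell, so a change in total RNA stays open and untested.

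The ABCE1 libraries listed more genes above 0 (29743 and 30047) than the controls (28207 and 27881) or the YAE1 libraries (28754 and 28865). Depth argues the other way, as the lowest ABCE1 total was 0.85 of the highest control total. A uniform background, such as genomic DNA, would add the same FPKM at every level of expression. The mean gain at 0.2 to 0.5 FPKM was instead 3.64 times that at 0.05 to 0.1 FPKM (95% bootstrap interval over genes 3.02 to 4.45), so such a background is unlikely to be the whole cause. A small background added to a proportional rise, and an effect of the ABCE1 guides themselves, stay open.

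The medians of the 3 cell-cycle lists were below 0 in both knockouts. With an estimated correlation, however, no list differed from other genes in camera (adjusted p = 0.13 to 0.17). With ABCE1 guides 41.9% of the G1 list, 50.3% of the S list and 45.4% of the G2M list were called lower. Called higher were 30.8%, 16.9% and 27.6%. Of all 12578 genes 2563 were lower and 4715 higher. These are an unlike baseline, because list genes were on average more abundant in the controls and abundant genes were more often lower. Among 10000 random lists matched on mean expression, and again on gene model length, the largest one-sided p of the 6 list medians was 0.0001, the smallest these draws can give, which argues against either property as the cause. Random lists ignore the correlation among cell-cycle genes, while camera with an estimated correlation rests on only 3 residual degrees of freedom. Whether a smaller share of cells in S phase is involved cannot be told, nor separated from a fall in dividing cells in general. The S median minus the G1 median was -0.136 with ABCE1 guides and -0.113 with YAE1 guides in the main lists. In the stricter lists it was 0.133 and 0.071, and there the G2M medians lay lowest (-0.446 and -0.578).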

How the results depend on the processing

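Of 444 values computed under the alternatives, 418 kept their direction and their side of the threshold, stayed within 1.5 times a count or, for the correlation of the knockout changes, within 0.0157 (its SD over the fits that leave out 1 library), and 2 reversed. All 102 values of the cell-cycle lists, with camera's preset correlation, and 187 of 192 values of the named genes were among the 418. This agreement is partly built in. Robust moderation, the replicate block and using only the compared libraries leave the fold changes as they were. Voom keeps the same library totals, and the named genes were chosen for large changes. The bound of 1.5 times a count also lets a split turn, as centring did for YAE1 guides (4303 higher and 2214 lower to 3014 and 3124). An estimated correlation was run only for the lists and settings of the report. There the 6 list calls against control were lost, on 3 residual degrees of freedom (camera, adjusted p = 0.13 to 0.17). The other 5 values of named genes were YAE1 against ABCE1 differences: the call for ENSG00000117724 was lost in 3 alternatives, and 2 differences that had not passed changed sign. Leaving out 1 library gave -0.293 to 0.132 for ENSG00000175426 and -0.051 to 0.193 for ENSG00000148773. Alternatives chosen after seeing the data were voom on recovered fragments, the stricter lists, the removal of the 20 highest genes and a separate control library for each knockout, which gave correlations of 0.746 and 0.755. With no filter, which tests 38269 genes, the YAE1 against ABCE1 counts were 907 higher and 1184 lower and the correlation of the knockout changes was 0.762. With a mean of at least 5 FPKM, which tests 7047 genes, 2845 genes were higher with ABCE1 guides, 2621 with YAE1 guides and 2058 in both, and the correlation was 0.845. Median centring gave 3915 lower genes with ABCE1 guides, 2085 higher in both and 2447 lower in both. Quantile normalization gave 2180 higher in both and a correlation of 0.795, and voom a correlation of 0.837. The cause of the changes in correlation was not tested. Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 835 to 1641 higher and 976 to 2080 lower genes for YAE1 against ABCE1, 3754 to 4862 and 1937 to 2697 for ABCE1 against control, 3037 to 4049 and 1509 to 2140 for YAE1 against control, and correlations of 0.779 to 0.824. Same-numbered libraries did not deviate together (r = -0.053, -0.013 and -0.009 between groups), so no effect of the replicate number was seen. Whether they were made together cannot be told from these values. With the replicate number as a block the counts were 4579 and 2479, 4130 and 2134, and 1675 and 2103. Leaving out mitochondrially encoded genes and the tests of symbol lists and targeted genes were not run. Other splits of the samples were not counted because groups hold 2 libraries. Depth limits the least abundant genes tested: at their 5th percentile of 15.8 fragments per library, counting alone gave an error of 25.2%.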

Other observations

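The values in this part were chosen after the data were seen. Genes below the tested range were not tested one by one. The mean FPKM of 3640 genes at 0.1 to 0.2 FPKM was 35.6% above control with ABCE1 guides and 12.8% above with YAE1 guides, and that of 2629 genes at 0.5 to 1 FPKM was 27% and 14.7% above. With ABCE1 guides 62% and 65.4% of these genes had a higher mean than in the controls, and with YAE1 guides 57.3% and 63.1%. Of the 31176 genes listed at 0 in both controls, 1373 were above 0 in both ABCE1 libraries and 941 in both YAE1 libraries. In the other direction, 525 genes above 0 in both controls were listed at 0 in both ABCE1 libraries and 626 in both YAE1 libraries. Among the genes listed at 0 in both controls, 17 reached at least 1 FPKM in both ABCE1 libraries and 4 in both YAE1 libraries, and in the other direction 3 and 6 genes of at least 1 FPKM in both controls were listed at 0.

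Of the 123 genes called in opposite directions, 41 were higher with ABCE1 guides and lower with YAE1 guides and 82 the reverse. The 20 most abundant genes of each library held 16.4% of the summed FPKM in both controls, 16.3% and 16.1% in the ABCE1 libraries and 18.7% and 18.3% in the YAE1 libraries. In 3 classes of recovered gene model length of about equal size, the median log2 change with YAE1 guides was 0.141, 0.102 and 0.061 from the shortest to the longest class, and with ABCE1 guides 0.104, 0.080 and 0.109.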
